A study of Homo sapiens with 6 samples.

How the data were processed

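Total RNA from 6 samples of the NCI-H2023 line was amplified, labelled with biotin and hybridised to expression arrays, 1 array per sample, per the labels' protocols. The values used here are the deposited log2 values, 1 per probe set and array, which the submitters' processing notes say were made with RMA, a method that corrects background, normalizes arrays to a common distribution and summarises probes. The version of RMA is not given in the sources used here. The notes also name the genome build hg38. RMA makes the arrays' distributions alike, so a change in the total amount of messenger RNA cannot be seen in these values, and dim probe sets have changes pulled toward 0 by background signal. The deposited table has 21448 probe sets. A platform annotation table names 1 gene for 17709 of them and several genes for 0, and 3739 are unnamed here. All 17709 gene identifiers matched RefSeq genes of the GRCh38 assembly, from which symbols and gene coordinates were taken. Where a gene had several probe sets, the one with the highest mean over all samples was kept, which left out 22 and gave 17687 genes. No filter on dim genes was applied, and the deposited values were not normalized again. Signals ran from 1.99 to 18.49, and the array medians from 6.21 to 6.23.

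Samples were grouped by their titles into control, miR-223-3p and miR-29a-3p, 2 each. The labels give no batches, slides or scan dates. No array was a copy of another, and no pair shared more than 259 equal values. Samples of one group differed by an SD of 0.337 to 0.374 (log2) across genes, and samples of different groups by 0.3581 to 0.4205. The number of arrays limits the precision. The median residual SD over genes was 0.226 at mean signals under 4, 0.264 at 4 to 6 and 0.111 above 12.

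Each of the 3 contrasts was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 fit of all 6 samples with 3 residual degrees of freedom, with the default constant prior and no blocking factor, and Benjamini-Hochberg adjustment over 17687 genes at 0.05. The fit that lets the prior variance follow the mean signal, called the intensity trend in the results, was among the alternatives. Fold changes are 2 to the power of the log2 difference of group means. Standard errors are those of the moderated test. The design, the alternatives, the rule for naming genes and 29 gene lists were fixed before the data were examined. The lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 29 lists of a contrast, and a list was called at an adjusted p under 0.05. Camera with an estimated correlation, camera on ranks and fry were the alternatives. No list call of camera held with an estimated correlation, where the test has 3 residual degrees of freedom. For the lists called in any contrast the estimates ran from -0.0244 for the miR-223-3p targets to 0.36 for histones. They were 0.329 for NRF2 genes, 0.133 for cholesterol genes and 0.1045 for YAP and TAZ genes. These last 3 and histones lay above the preset. So did NF-kB genes at 0.0669, epithelial markers at 0.0303 and interferon-stimulated genes at 0.0135. Camera at the preset may overstate the evidence for all of these lists. For each list the members past the gene test were counted over all genes and adjusted over the list alone. The target lists were drawn from textbook and review knowledge, not from these samples.

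Named genes follow this rule. For each mimic against control they are the 10 largest rises and 10 largest falls among genes past the threshold whose mimic samples both lay on the same side of both control samples, and between the mimics the 5 and 5. Where none passed in a direction, the 5 with the smallest p are given as values. Up to 4 members of each called list and up to 6 of each published target list of a mimic are named, with a fixed set of well-known targets. STMN1, in that set, was not among the genes tested. The rule was applied again to the fit with the intensity trend, a step chosen after seeing the data, as were the other list members named in the text with their values and the genes shared by both mimics.

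Other alternatives were leaving out dim genes, a second quantile normalization, centring arrays on their medians, a robust prior, fitting only the groups compared, the replicate letter as a block, array weights, all probe sets, an unadjusted threshold with a 1.5-fold minimum and leaving out each sample in turn. Where that left a group with 1 sample, limma's pooled spread was used, which assumes that the lone sample varies like the others. Overlap of the responses was set against 100 simulated draws of unchanged groups that share the control samples. A planned comparison of genes with and without seed sites in their 3′ untranslated regions was not run, since transcript sequences were not used here.

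The procedure was tested on simulated data with 200 changed genes of 17687 in the design of miR-223-3p against control, in 10 sets. With the constant prior it recovered 1.19% of genes changed 1.5-fold, 34.3% of those changed 2-fold and 88% of those changed 3-fold, and 2.27% of its calls were unchanged genes. With the intensity trend it recovered 14.8%, 57.3% and 94.7%, and 4.47% of its calls were unchanged genes. Noise was drawn independently for each gene around a curve of residual SD over signal level. The curve was fitted to square roots of the residual SDs, which gives values below their root mean square, so recovery may be overstated. The noise followed signal level by design, which suits the intensity trend, so its share of unchanged genes may differ in the real data.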

Results

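Gene expression was measured on arrays in NCI-H2023, a human lung adenocarcinoma cell line, after reverse transfection with 1 of 3 small RNAs. The 3 groups were a negative control, a synthetic mimic of miR-223-3p and a synthetic mimic of miR-29a-3p, with 2 samples each, lettered A and B. Per the labels' protocols each RNA was used at 0.5 nM and the medium was changed at 24 h. The labels call the control a mimic control in the sample titles and a negative control siRNA in the protocol. The labels give no time of harvest, and A and B are called experimental replicates with nothing said of separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. Values for 17687 genes were compared. The array medians lay between 6.21 and 6.23 on the log2 scale, and samples of one group correlated across genes at 0.9938 to 0.995. Samples of different groups correlated at 0.9922 to 0.9943, so the ranges overlap. With 2 arrays per group, the number of arrays limits the precision. The mature microRNAs were not among the genes tested, so the amount of each mimic in the cells was not measured here.

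The first comparison asked how the transcripts of these cells differed with the miR-223-3p mimic and with the control. Lower signals with the mimic were found for the miR-223-3p targets PARP1, a poly(ADP-ribose) polymerase of DNA repair, by 2.48-fold, and FBXO8, an F-box protein, by 2.25-fold. Signals of MANBAL and of TSPAN7, a tetraspanin, were each 3.14-fold lower. Signals were 3.64-fold higher for UPK3B, a uroplakin of the cell surface, 3.41-fold higher for DSC2, a desmosomal cadherin, and 2.20-fold higher for EPCAM, an epithelial adhesion molecule. None of these genes passed the moderated limma test with a constant prior, where the smallest adjusted p was 0.0855. All of them passed when the prior followed the signal level, an alternative fixed in advance.

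In detail, PARP1 (gene ID 142, GRCh38 chromosome 1, 226360691 to 226408093) measured 10.51 ± 0.0071 in control and 9.195 ± 0.0212 with the mimic (log2, SD, n = 2 each). Its log2 change was -1.31 with a standard error of 0.178. The adjusted p in limma was 0.168 with the constant prior and 0.000553 with the intensity trend. MANBAL (chromosome 20, 37289655 to 37317260) changed by -1.65 with a standard error of 0.179, and its adjusted p was 0.0855 and 7.6e-06 in the same order. UPK3B (chromosome 7, 76510552 to 76516522) changed by 1.865 with a standard error of 0.212, with adjusted p of 0.0855 and 0.00203. Other genes lower with the mimic and called with the intensity trend were SLC39A14, a zinc and metal transporter, the Wnt antagonist DKK1, the bicarbonate transporter SLC4A4, STC1, ARPP19, ceruloplasmin (CP) and the ubiquitin ligase WWP1, with log2 changes from -1.355 to -1.19. Higher genes called in that fit were the iron-binding lipocalin LCN2, KIAA0040, the adhesion molecule CEACAM1, the steroid sulfatase STS, TBPL1, IL1RAP, a subunit of the interleukin-1 receptor, and CSGALNACT2, with log2 changes from 1.15 to 1.56.

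Published targets of miR-223-3p were lower as a group. Of 31 members measured, 22 lay below control and 9 above, and the list mean was -0.275 in sample A and -0.25 in sample B relative to the control mean. The adjusted p of camera was 0.000376, and it was 0.453 with an estimated correlation, a test that has 3 residual degrees of freedom here. Over all genes no member passed, and adjusted over the list alone 4 members were lower, which were PARP1, FBXO8, NFIA and MSMO1. The same 4 were called over all genes with the intensity trend. NFIA, a transcription factor of the nuclear factor I family, differed by -0.765 with a standard error of 0.181, and MSMO1, an enzyme of cholesterol synthesis, by -0.685 with a standard error of 0.183. RHOB differed by -0.84 and E2F1 by -0.64, neither past the test. FBXW7, FOXO1 and IGF1R, often studied as targets, differed by -0.255, -0.23 and -0.23, with adjusted p from 0.846 to 0.855 in limma.

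The epithelial markers were higher with the miR-223-3p mimic, with 16 of 22 members above control and list means of 0.28 and 0.175 in samples A and B. Adjusted over the list alone 2 members passed and over all genes none, while 2 passed over all genes with the intensity trend, EPCAM and the keratin KRT19, which differed by 0.82. The adjusted p was 0.0157 in camera and 0.66 with an estimated correlation, and it was 0.29 without sample A of the mimic, 0.116 without sample B of the control and 0.0662 on ranks. Genes induced by NRF2, the regulator of the antioxidant response, were lower, with 19 of 21 members below control and list means of -0.0876 and -0.242. No member passed over all genes or adjusted over the list alone. The transporter ABCC2, which differed by -0.59, was called with the intensity trend, and HMOX1, heme oxygenase, lay the other way at 0.62. The adjusted p was 0.0157 in camera and 0.842 with an estimated correlation. It was 0.173 without sample B of the control, 0.365 without sample B of the mimic and 0.15 after a second quantile normalization. The other 26 lists were not called, with adjusted p from 0.205 to 0.981. Among them were mesenchymal markers (mean -0.128, adjusted p = 0.22), leukocyte markers (adjusted p = 0.908) and fibroblast and endothelial markers (adjusted p = 0.55).

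Counted over all genes, limma with the constant prior called 0 genes, where 1343 of 17687 had an unadjusted p under 0.05 and 884 were expected by chance. The fit with the intensity trend called 121, of which 32 were higher and 89 lower. That count fell to 42 without sample A of the control, 49 without sample B of the control, 57 without sample A of the mimic and 55 without sample B of the mimic. The samples of the groups did not overlap for 36.9% of genes, against 33.33% by chance.

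**Figure D1:**
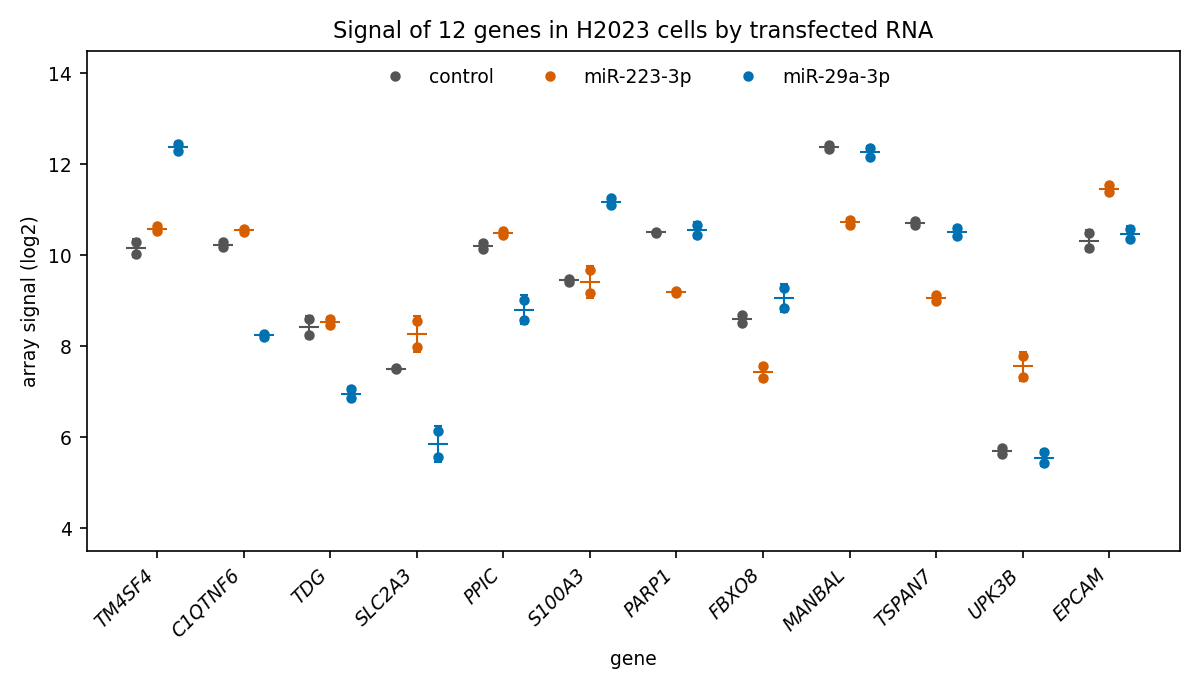
Array signal (log2, vertical axis) of 12 genes in the control, miR-223-3p and miR-29a-3p samples. Points are single samples, horizontal marks are group means and bars are 1 SD (n = 2). TM4SF4 lies at 12.46 and 12.29 with miR-29a-3p and at 10.3 and 10.03 in control, and the PARP1 samples with miR-223-3p lie below all other PARP1 samples.

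The second comparison set the miR-29a-3p mimic against the control. TM4SF4, a tetraspan membrane protein, rose 4.63-fold, from 10.16 ± 0.191 to 12.38 ± 0.12 (log2, SD, n = 2 each). C1QTNF6, a secreted protein of the C1q and tumor necrosis factor family, fell 4.0-fold, from 10.24 ± 0.0849 to 8.24 ± 0.0424. These were the 2 genes past the limma test with a constant prior, each with an adjusted p of 0.0142. When the prior followed the signal, TDG and TET2 of DNA demethylation were also called lower, TDG, the thymine DNA glycosylase, by 2.76-fold and TET2, a dioxygenase that oxidizes methylcytosine, by 1.93-fold. CHAC1, a glutathione-degrading enzyme of the stress response, was called 2.59-fold higher in that fit.

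TM4SF4 (gene ID 7104) lies on GRCh38 chromosome 3 from 149474697 to 149503394, and its log2 change was 2.21 with a standard error of 0.187. C1QTNF6 (gene ID 114904) lies on chromosome 22 from 37180166 to 37199423, and its log2 change was -2.0 with a standard error of 0.173. Without sample A or B of the control, or A or B of the mimic, the adjusted p of TM4SF4 was 0.182, 0.22, 0.297 and 0.247, and that of C1QTNF6 was 0.293, 0.22, 0.297 and 0.247. TDG (chromosome 12, 103965872 to 103988874) differed by -1.465 with a standard error of 0.198, with an adjusted p of 0.0918 with the constant prior and 0.00226 with the intensity trend. Further genes called lower with the trend were ELMO1, a regulator of engulfment and Rac, MAML3, a coactivator of Notch, albumin (ALB), CHRAC1, SLC16A14 and CARD10. Their log2 changes ran from -1.655 to -1.44. ALB had SDs of 0.771 in control and 0.502 with the mimic, and its adjusted p was 0.258 in limma with the constant prior. The glucose transporters SLC2A14 and SLC2A3 were also called with the trend, at -1.675 and -1.655. But they are near-identical neighbours whose probes may not tell them apart. They did not move alike with miR-223-3p, where the SLC2A3 mean was 8.275 (SD 0.403) against 7.51 in control and the SLC2A14 mean 8.415 against 8.51. Called higher were S100A3, LOXL1, a lysyl oxidase of elastic fibres, MCMDC2, FRMD3, DESI2, ANKRD1, KIAA0040 and the elongation factor EEF1A2, with log2 changes from 1.735 to 1.275.

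Published miR-29 targets outside the matrix were lower as a group, with 20 of 31 members below control and list means of -0.218 and -0.299 in samples A and B. The adjusted p was 0.000466 in camera and 0.399 with an estimated correlation. No member passed over all genes. Adjusted over the list alone 9 members were lower, including TDG, TET3 at -1.09, the histone demethylase KDM5B at -0.965, TET2 at -0.945, the cyclin-dependent kinase CDK6 at -0.84 and TRAF4 at -0.73. Over all genes 3 passed with the intensity trend, which were TDG, KDM5B and TET2. DNMT3A, DNMT3B, MCL1 and CDC42, also on this list, differed by -0.375, -0.25, -0.23 and -0.135, none past the test. The matrix targets of miR-29 were not called, with an adjusted p of 0.0821 in camera and 16 of 25 members below control. Adjusted over the list alone 3 of them were lower, which were the metalloprotease ADAM12 at -1.265, the collagen COL5A2 at -0.92 and the fibrillin FBN1 at -1.01. COL4A1 differed by -0.09 and COL4A2 by -0.135, while COL15A1 lay higher at 0.515. The adjusted p of the matrix list was 0.0443 without sample A of the control, 0.0499 without sample B of the mimic and 0.00242 without dim genes.

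Genes of cholesterol synthesis and uptake were lower with miR-29a-3p, with 18 of 20 members below control and list means of -0.337 and -0.224. Their changes were small, and none passed over all genes or adjusted over the list alone. HMGCS1, the hydroxymethylglutaryl-CoA synthase, differed by -0.675 and was the 1 member called with the intensity trend, and INSIG1 differed by -0.62. The adjusted p was 0.000466 in camera and 0.399 with an estimated correlation. Genes induced by the Hippo effectors YAP and TAZ were higher, with 14 of 19 members above control and list means of 0.316 and 0.284. Adjusted over the list alone 3 members were higher, the ecto-nucleotidase NT5E at 1.14, ANKRD1 at 1.31 and AJUBA at 0.655, and none passed over all genes. NT5E was higher with miR-223-3p too, with means of 11.19 in control, 12.32 with miR-29a-3p and 12.1 with miR-223-3p. ANKRD1 means were 5.005, 6.315 and 4.385 in the same order, and AJUBA means 8.765, 9.42 and 8.81. The adjusted p of this list was 0.000466 in camera and 0.399 with an estimated correlation.

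Inflammatory genes regulated by NF-kB were higher, with 15 of 22 members above control. The chemokines CXCL1 and CXCL8 differed by 0.945 and 0.915. CXCL8 was higher with both mimics, with means of 7.23 in control, 8.145 with miR-29a-3p and 8.005 with miR-223-3p. CXCL1 means were 8.99, 9.935 and 9.3 in the same order. With miR-29a-3p these 2 members passed adjusted over the list alone, and none passed over all genes. The adjusted p was 0.0387 in camera and 0.544 with an estimated correlation, and it was 0.232 without sample A of the mimic, 0.195 without sample B of the control and 0.122 on ranks. Replication-dependent histones were lower, with 19 of 23 members below control, but sample A of the control had a list mean of -0.16 and sample B of the mimic -0.163. The linker histone H1-5 differed by -0.56 and was called with the intensity trend, and no member passed over all genes or adjusted over the list alone. The estimated inter-gene correlation of this list was 0.36, against the preset 0.01. The adjusted p was 0.00689 in camera and 0.805 with an estimated correlation, 0.224 without sample A of the mimic and 0.783 without sample B of the control. The unfolded protein and integrated stress response list was not called (adjusted p = 0.0821, mean 0.178, median -0.005). Its 5 members called higher adjusted over the list alone were CHAC1 at 1.375, the cystine transporter SLC7A11 at 0.875, and the amino acid synthesis enzymes PHGDH, ASNS and PSAT1 at 0.905, 0.73 and 0.58. The 24 lists not called had adjusted p from 0.0821 to 0.982, with leukocyte markers at 0.308 and fibroblast and endothelial markers at 0.604.

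With the constant prior limma called 2 genes, 1 higher and 1 lower, and 1567 had an unadjusted p under 0.05 against 884 by chance. The fit with the intensity trend called 182, of which 59 were higher and 123 lower. This count fell to 51 without sample A of the control, 81 without sample B of the control, 55 without sample A of the mimic and 45 without sample B of the mimic.

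**Figure D2:**
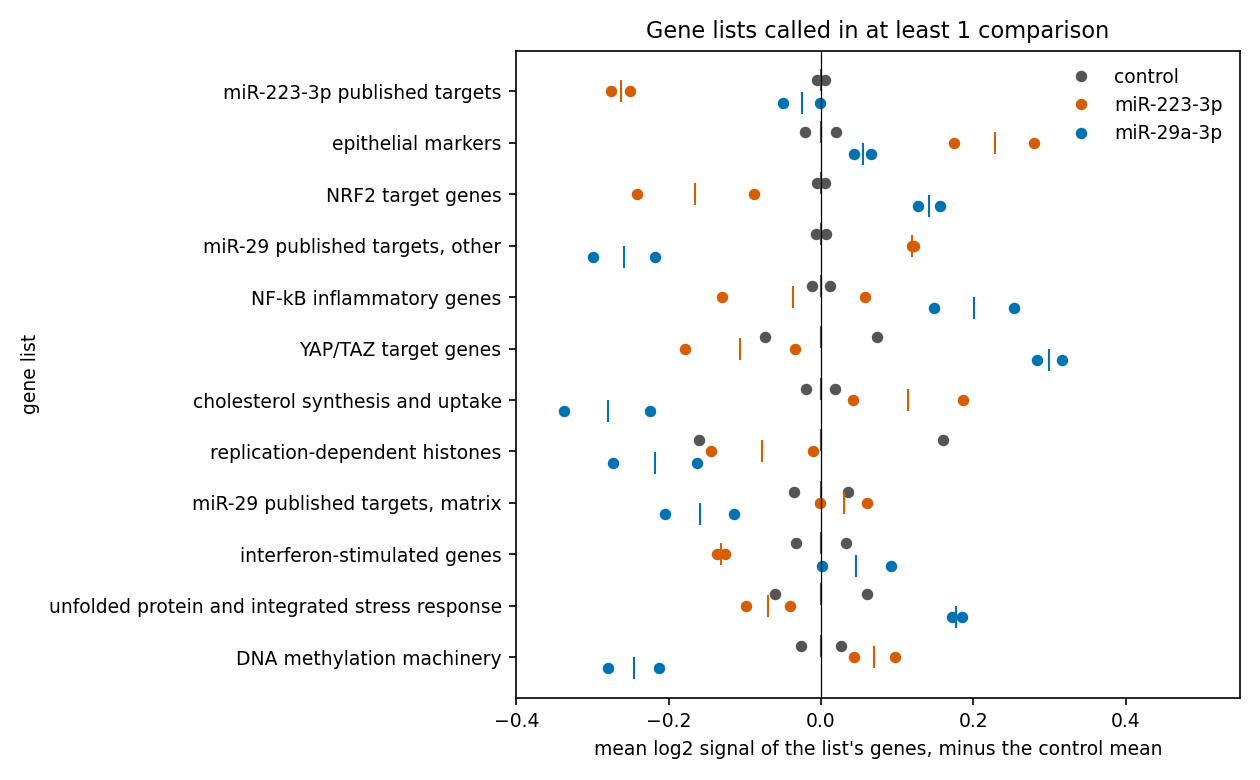
Mean log2 signal of each gene list minus the mean of the control samples (horizontal axis) for the 12 lists called in at least 1 comparison. Points are single samples and vertical ticks are group means (n = 2). The miR-223-3p targets lie at -0.275 and -0.25 with miR-223-3p, and the non-matrix miR-29 targets at -0.218 and -0.299 with miR-29a-3p.

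The third comparison set the mimics against each other, which tests their difference directly. It does not tell which mimic moved away from control. With miR-29a-3p, SLC2A3 was 5.35-fold lower than with miR-223-3p, C1QTNF6 4.96-fold lower and UPK3B 4.03-fold lower, and the cyclophilin PPIC and the glycosyltransferase POGLUT2 were 3.23-fold and 3.06-fold lower. ANKRD1, a YAP-induced nuclear protein of muscle and other cells, was 3.81-fold higher, GLP2R, the glucagon-like peptide-2 receptor, 3.76-fold, TM4SF4 3.46-fold, S100A3 3.4-fold and FBXO8 3.12-fold. All 10 passed the limma test with a constant prior, with adjusted p from 0.00878 for C1QTNF6 to 0.0411 for ANKRD1. SLC2A3 and its near-identical neighbour SLC2A14 may share probe signal. PARP1 (log2 difference 1.365, standard error 0.178) and TDG (-1.58, standard error 0.198) were called too, each with an adjusted p of 0.0326.

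The non-matrix miR-29 targets were lower with miR-29a-3p than with miR-223-3p (24 of 31 members, mean log2 difference -0.379). Against control their mean was -0.259 with miR-29a-3p and 0.12 with miR-223-3p, so part of the difference was a rise with miR-223-3p. Between the mimics their adjusted p was 4.77e-07 in camera and 0.22 with an estimated correlation. TDG passed over all genes and 8 members adjusted over the list alone, among them INSIG1 at -1.075, the phosphatase PPM1D at -0.96 and TET3 at -0.96. The matrix targets were lower as well (adjusted p = 0.0347, and 0.264 with an estimated correlation), with COL5A2 at -0.945, LAMC1 at -0.78, ADAM12 at -0.795 and the collagen chaperone SERPINH1 at -1.025 among 6 members lower adjusted over the list alone, and none over all genes. That call was lost without sample A of miR-29a-3p (0.151) or of miR-223-3p (0.176). The miR-223-3p targets were higher with miR-29a-3p (20 of 31 members, mean 0.237, adjusted p = 0.00586, and 0.253 with an estimated correlation). FBXO8 and PARP1 passed over all genes, and 3 members were higher and 1 lower adjusted over the list alone, with RHOB at 1.365 and HMGCS1 at -0.695.

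Cholesterol genes were lower with miR-29a-3p than with miR-223-3p in 18 of 20 members. Adjusted over the list alone 5 passed, INSIG1, the squalene epoxidase SQLE at -0.835, HMGCS1, MVK and IDI1. SQLE means were 11.09 in control, 10.76 with miR-29a-3p and 11.6 with miR-223-3p, and MVK means 7.735, 7.46 and 8.17. Both differed more through higher values with miR-223-3p. INSIG1 means were 8.745, 8.125 and 9.2 in the same order. HMGCS1 means were 12.04, 11.36 and 12.05, so it was lower with miR-29a-3p only. The list's adjusted p was 1.14e-06 in camera and 0.253 with an estimated correlation. YAP and TAZ genes were higher in 16 of 19 members, with ANKRD1 past the test over all genes and CCN1 at 1.085, LATS2 at 0.705 and AJUBA at 0.61 among 4 adjusted over the list alone (adjusted p = 4.61e-06 in camera, and 0.253 with an estimated correlation). CCN1 and LATS2 differed mainly through lower values with miR-223-3p. Their means were 8.115 and 9.295 in control, 8.34 and 9.065 with miR-29a-3p, and 7.255 and 8.36 with miR-223-3p. NRF2-induced genes were higher in 19 of 21 members (adjusted p = 2.11e-05 in camera, and 0.421 with an estimated correlation). Adjusted over the list alone 4 passed, GCLM at 0.9, OSGIN1 at 0.905, ABCC2 at 0.74 and SLC7A11 at 0.605. ABCC2 differed mainly through lower values with miR-223-3p, with means of 14.53 in control, 14.68 with miR-29a-3p and 13.94 with miR-223-3p. SLC7A11 means were 14.16, 15.04 and 14.44 in the same order. GCLM means were 11.59, 12.06 and 11.16, and OSGIN1 means 11.91, 12.26 and 11.36. The unfolded protein and integrated stress response list was higher (17 of 25 members, adjusted p = 0.00176, and 0.253 with an estimated correlation), with the mTOR inhibitor DDIT4 at 1.31, CHAC1 at 0.92 and ASNS at 0.905 among 5 members adjusted over the list alone. HMGCS1, MSMO1 and INSIG1 stand on a target list and on the cholesterol list, so these tests share genes.

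NF-kB genes were higher (15 of 22 members, adjusted p = 0.0107, and 0.403 with an estimated correlation), with CCL2 at 1.14 and ICAM1 at 0.88, and 2 members passed adjusted over the list alone. CCL2 means were 10.32 in control, 10.62 with miR-29a-3p and 9.485 with miR-223-3p, and those of ICAM1 were 12.51, 12.79 and 11.91. Interferon-stimulated genes were higher (20 of 31 members, adjusted p = 0.0153, and 0.264 with an estimated correlation), with HERC5 at 0.615, IFI44L at 0.92 and MX1 at 0.525, none of which passed. Genes of DNA methylation and demethylation were lower (10 of 15 members, adjusted p = 0.0107, and 0.253 with an estimated correlation), with 5 lower and 1 higher adjusted over the list alone. The de novo methyltransferase DNMT3A was among the lower, at -1.015, and TDG and the TET genes are also on the miR-29 list. DNMT3A means were 9.115 in control, 8.74 with miR-29a-3p and 9.755 with miR-223-3p. Most of its difference was thus a rise with miR-223-3p. Without sample A of miR-29a-3p the adjusted p was 0.151 for NF-kB genes and 0.0641 for DNA methylation genes. Without sample A of miR-223-3p it was 0.0575 for the interferon and for the DNA methylation genes. Without sample B of miR-29a-3p it was 0.169 for the interferon genes, and without sample B of miR-223-3p 0.159 for the NF-kB genes. On ranks camera gave an adjusted p of 0.0802 for the miR-223-3p targets, 0.262 for the matrix targets and 0.139 for the DNA methylation genes. The remaining 19 lists had adjusted p from 0.0656 to 0.95, with leukocyte markers at 0.417 and fibroblast and endothelial markers at 0.95.

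In this comparison 39 genes passed with the constant prior, 24 higher and 15 lower with miR-29a-3p, and 344 with the intensity trend, 182 higher and 162 lower. The count of 39 fell to 1 without sample A or sample B of the control, which contribute only to the shared spread, and to 0 without any 1 of the mimic samples. The count of 344 fell to 141 and 162 without sample A and B of miR-29a-3p, and to 217 and 150 without sample A and B of miR-223-3p.

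**Figure D3:**
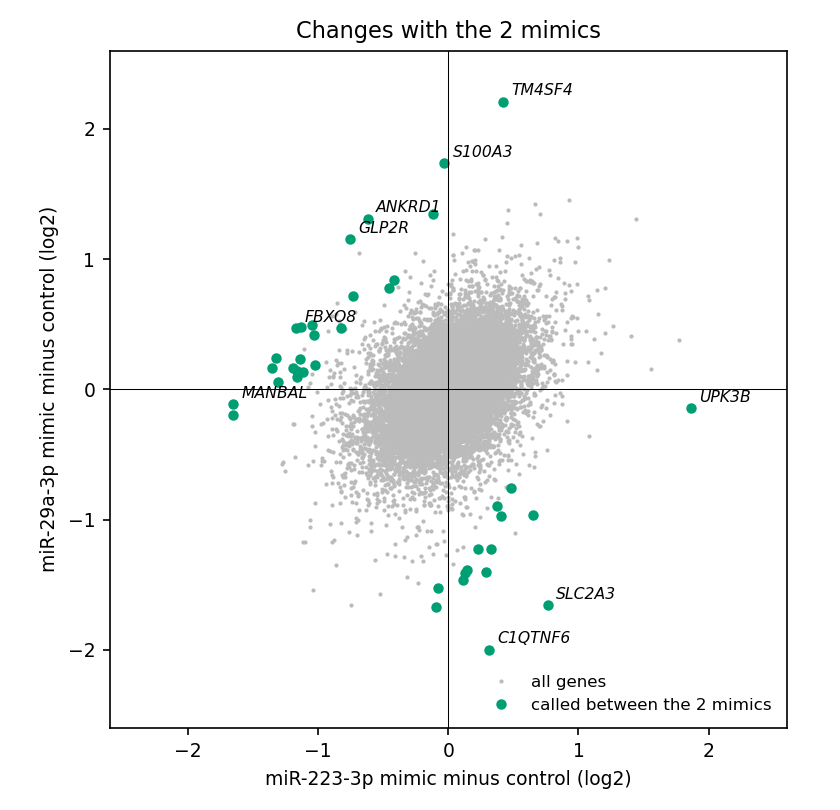
Log2 change of each gene with miR-223-3p (horizontal axis) and with miR-29a-3p (vertical axis), both against the control. Small grey points are all 17687 genes and larger points are the 39 genes called between the mimics, which were selected for their difference. UPK3B lies at 1.865 on the horizontal axis and TM4SF4 at 2.21 on the vertical axis.

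The responses to the mimics were then compared with each other. Both use the same control samples, so a positive relation arises with no effect at all. Across genes, which are not independent replicates, the log2 changes correlated at 0.408, against 0.5 simulated for unchanged groups sharing these controls, and 64.57% of the genes with a sign in both had the same sign, against 66.71% simulated. With noise taken from the control samples alone, a setting added after seeing the data, the simulated share was 62.91%, so the observed share lay below or above it by the setting. No sign was given to 263 genes whose group means were equal in at least 1 comparison. The covariance was 0.0339, against 0.0318 simulated with an SD of 0.000808. The difference of 0.00209 became -0.00793 without sample A of the control and -0.00114 without sample B of the control. In those fits the control noise was simulated from the spread of the mimic samples alone. With the constant prior no gene was called against control with both mimics. With the intensity trend 18 genes were called in the same direction and 0 in opposite directions, against 0.726 and 0.519 for independent lists. Unchanged groups sharing the controls gave a mean of 0.01 and 0 such genes over 100 simulated draws. These genes, 9 higher and 9 lower, include the nucleotidase NT5E, KIAA0040, TBPL1, DESI2, the complement factor CFI, the RNA sensor IFIH1, the deiodinase DIO2 and ELMO1. The controls could not be split into parts of 2 samples, so part of the excess may come from the shared controls. The simulated value leaves out the effects and that of independent lists leaves out the shared controls, so neither gives the number expected for separate effects measured against the same controls.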

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

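The test of a response common to both mimics was chosen after the result was seen. The metallothionein list was also chosen after seeing the data.

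Among the 3739 probe sets without a gene name here, which the comparisons did not use, 3 differed between the mimics past the adjusted threshold, with the miR-223-3p samples above both control samples and the miR-29a-3p means below the control mean. Probe set TC0100017167.hg.1 differed by -1.58 (miR-29a-3p minus miR-223-3p, log2, adjusted p = 0.0424 in limma), with means of 6.675 with miR-29a-3p, 8.255 with miR-223-3p and 7.31 in control. Probe set TSUnmapped00000293.hg.1 differed by -1.535 (adjusted p = 0.0424), with means of 12.34, 13.88 and 13.6 in the same order. Probe set TSUnmapped00000336.hg.1 differed by -1.42 (adjusted p = 0.0426), with means of 11.36, 12.78 and 12.57. In the last 2 the miR-29a-3p mean lay farther from control than the miR-223-3p mean did. No gene was assigned to them and no explanation was tested.

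Published miR-223-3p targets were lower with that mimic (mean log2 change -0.262, adjusted p = 0.000376 in camera) and the non-matrix miR-29 targets with miR-29a-3p (-0.259, adjusted p = 0.000466). With an estimated correlation neither list passed (0.453 and 0.399), and the miR-29 matrix targets were not called in camera (0.0821). A bias that depends on signal is argued against, since 0% of 10000 random lists matched on signal had means as low, in either case. A response common to both mimics is argued against too: the list mean with the own mimic minus that with the other mimic was -0.237 and -0.379, and its highest value over both lists and the 6 fits without 1 sample was -0.213. The controls cancel in this difference, so the fits without a control sample repeat the main values and add no support. Part of the -0.379 was a rise of the non-matrix miR-29 targets with miR-223-3p. Their mean there was 0.12, with 23 of 31 members above control (adjusted p = 0.205 in camera). That mean lay above 99.4% of the random lists matched on signal. The miR-223-3p targets had a mean of -0.0252 with miR-29a-3p. Direct pairing of the mimic with these transcripts is a biological hypothesis, and seed sites, which would bear on it, were not analysed here. Whether the lower level comes from pairing or from a secondary response to each mimic stays open.

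Metallothioneins, small metal-binding proteins encoded side by side on chromosome 16, were lower as a group with miR-29a-3p (mean of 9 members -0.606, adjusted p = 7.24e-08 in camera over 6 such tests, and unadjusted p = 0.0315 with an estimated correlation, on a list chosen from these data). The value with an estimated correlation was not adjusted over the 6 tests, unlike the first, so it is not a call. No member passed the main limma test, where the lowest adjusted p was 0.229 for MT1X, and 4 were called with the intensity trend. MT1F differed by -0.965 and MT1X by -0.765, while the MT3 samples overlapped those of control. With miR-223-3p the mean was -0.01. If the probe sets read near-identical transcripts as 1 signal, members would change alike, but with miR-223-3p their changes spanned 1.02, from -0.675 for MT1E to 0.34 for MT2A, a range that 2.71% of simulated sets of 9 reached. That range rests on MT1E, which had an SD of 0.311 in control. The other members lay from -0.085 for MT1H to 0.34, so the test speaks for MT1E only. With miR-29a-3p the span was 0.53, which noise alone gave in 50.6% of simulated sets, so partial cross-hybridisation may still tie some members together. No biological explanation was tested.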

How the results depend on the processing

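The alternatives with the intensity trend on lists and their members, named genes and overlap, its own filter, normalization, block and left-out samples, and the overlap with control noise alone, were chosen after seeing the data. Gene counts are given for miR-223-3p against control, miR-29a-3p against control and miR-29a-3p against miR-223-3p in that order. Against 0, 2 and 39 with the constant prior, limma called 2, 4 and 95 without dim genes, 121, 182 and 344 with the intensity trend, and 684, 826 and 1022 at an unadjusted p and 1.5-fold. With only the groups compared it called 1 in the last. Ranges without 1 sample were 0 to 0, 0 to 2 and 0 to 1, and with the trend 42 to 99, 45 to 189 and 141 to 336. Centring, robust prior, second quantile normalization and array weights kept each count within 1.5-fold. The same letter gave correlations of deviations of 0.068, 0.0039 and 0.13 between groups, so the letters were not taken to pair samples. With the replicate block the counts were 0, 0 and 0 (adjusted p = 0.0742 for TM4SF4 and for C1QTNF6), and 276 for miR-29a-3p against control with the intensity trend.

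Lists called by camera numbered 3, 5 and 10. With an estimated correlation 0, 0 and 0 were called and with fry 1, 0 and 3, and the intensity trend gave 10 for miR-29a-3p against control. Ranges without 1 sample were 1 to 4, 3 to 8 and 7 to 11. The adjusted p of the miR-223-3p targets was 0.453 with an estimated correlation and 0.000781 to 0.00941 without 1 sample. For the non-matrix miR-29 targets it was 0.399 with an estimated correlation, 0.0836 with fry and 0.00115 to 0.0145 without 1 sample. The matrix targets, not called, reached 0.00242 without dim genes and 0.0359 with the intensity trend, and lay between 0.0443 and 0.355 without 1 sample. The covariance excess of 0.00209 was 0.00453 without dim genes, 0.00438 with the replicate block, 0.0053 with control noise alone, and from -0.00793 to 0.00478 without 1 sample, with -0.00793 and -0.00114 for sample A and B of the control. COL4A1 changed sign without sample A of the control (0.025) and without sample A of miR-29a-3p (0.235), with values from -0.415 to 0.235. Of 2055 alternatives of 147 named results, 1822 kept direction and side of the threshold, 148 lost the call, 83 gained it and 2 turned sign. A gene not called in the main fit that stayed uncalled counts as kept. Against control only TM4SF4 and C1QTNF6 were called in the main fit, so the 1822 does not measure how well calls held. Leaving out samples or genes alters the spread, the prior and the number of tests together, and counts moved both ways. What caused a change in count was not tested. The median residual SD was 0.226 at signals under 4, 0.264 at 4 to 6 and 0.111 above 12, and what this noise does to each result was not tested. The seed-site alternatives were not run.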

Other observations

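The list of acute-phase and complement genes was chosen after seeing the data. Secreted plasma proteins of the acute-phase and complement groups went both ways with miR-223-3p. Of 18 measured, 11 lay below control and 7 above (mean -0.17, adjusted p = 0.0194 in camera over the 6 tests of lists chosen this way, and unadjusted p = 0.0815 with an estimated correlation). Of these, 5 were called lower with the intensity trend, ceruloplasmin (CP) at -1.255, the complement factors CFI at -1.1 and C5 at -0.655, and the fibrinogen chains FGB at -0.61 and FGA at -0.395, and LCN2, which binds bacterial siderophores, was called higher at 1.56. With miR-29a-3p the mean was -0.139 (adjusted p = 0.249 in camera). CFI at -1.175 and the orosomucoid ORM1 at -0.925 were called lower with the intensity trend, although ORM1 and ORM2 are near-identical copies. Output genes of the MAPK pathway, a list fixed in advance and not called between the mimics (adjusted p = 0.0833), held 4 members higher with miR-29a-3p than with miR-223-3p adjusted over the list alone, FOSL1 at 1.735, CCND1 at 1.205, ETV5 at 0.96 and MYC at 0.65, of which CCND1 also passed over all genes.

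A hypothesis was that the mimics move genes in opposite directions, since 34 of the 39 genes called between them had opposite signs against control. Those genes were selected for their difference, and among all genes 6174 had opposite and 11250 the same signs, and 263 had no change with 1 or both mimics. The covariance of the responses exceeded the simulated shared-control value by 0.00209, and a value of 0 or above had been set beforehand as speaking against the hypothesis. The excess turned to -0.00793 and -0.00114 when 1 control sample was left out. In those fits the control noise was simulated from the spread of the mimic samples alone, so that turn of sign cannot decide the question. With control noise alone, a setting added after seeing the data, the excess was 0.0053. The bound was still too strict, because the simulated SD of 0.000808 leaves out the error in the noise of 2 controls. The 18 genes called in the same direction with the intensity trend, against 0 in opposite directions, go against the hypothesis too. But noise in the shared controls pushes calls the same way, and no value here separates that noise from the effects. Whether the responses are opposed, alike or unrelated over all genes stays undecided. A second hypothesis was that the larger counts with the intensity trend come from noise that depends on signal. In data simulated with noise that depends on signal, the trend recovered 1.35 times the changed genes of the constant prior, with 4.47% of its calls unchanged genes. A ratio of 1.5 or less had been set beforehand as speaking against the hypothesis. That bound did not account for the mix of fold sizes, which fixes the ratio: recovery was 14.8% against 1.19% at 1.5-fold and 94.7% against 88% at 3-fold. The sizes of the true changes are not known, so this noise may account for the larger counts or for part of them.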
